A study of Rattus norvegicus with 6 samples.

How the data were processed

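Shunt collateral arteries and control arteries of the rat hindlimb were compared on 2-colour Agilent oligonucleotide arrays. Per the labels, the arteries were snap-frozen, total RNA was extracted and linearly amplified, and the shunt and control RNA of 1 rat were labelled with Cy3 and Cy5 and hybridised together. There were 3 rats (rats 8, 15 and 17, replicates 1, 2 and 3) with 2 arrays each, 6 arrays in all. Each rat is a separate animal. The 2 arrays of a rat hold the same pair of extracts and were counted as 1 replicate. Per the labels, the dyes were exchanged between the arrays of rat 8 and between those of rat 17, and shunt RNA was in Cy5 on both arrays of rat 15.

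Per the submitters' processing notes, the scans were read with Agilent Feature Extraction version 7.5.1. The deposited scanner tables hold, per the file headers, the mean intensity of each spot and the median of its local background for each dye, with no normalization. They also hold processed intensity values, which the software had background-subtracted and dye-normalized, with surrogates for low values, and a log10 ratio of Cy5 over Cy3 from them, per the file headers. Other deposited columns are 0 or 1 marks for spots well above background, saturated spots and outlier spots, per the file headers. The header's background method code was 5 on the first 3 arrays and 7 on the last 3, which correspond to 2 extraction sessions. The value table of the series, also from the authors, was set against the scanner ratios of each array. Its correlation with Cy5 over Cy3 was 0.903, -0.919, 0.915, 0.914, 0.956 and -0.843 on the 6 arrays, over spots well above background in both dyes, so its values already run as shunt over control by the labels. The SD of its values was 0.287 to 0.468 times that of the log2 ratios, so a log10 scale is likely but not settled, and its centring is not known. The column medians were 0.042, -0.042, 0.041, 0.022, 0.0065 and -0.037, and the values were multiplied as log10 ratios to the log2 scale for use as an alternative.

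The mean intensities were corrected for background with normexp (offset 50), control spots were then left out, and spots marked as outliers in either dye were set to missing. Saturated spots were kept. Each array was normalized by loess, ratios were turned to log2 shunt over control by the labels, spots of a probe were averaged, and the arrays of a rat were averaged. Calculations were made in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table. A probe was tested if it was well above background on at least 3 of the 6 arrays in the shunt channel or on at least 3 in the control channel. Of 41012 probes, 20542 met this and 20515 had a value in both rats fitted. Rat means were tested against 0 with limma's moderated test, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 rats, a probe's own variance rests only on the difference between the rats. The variance pooled over probes entered with 7.49 prior degrees of freedom, so SE and p rest mostly on that pooled variance. Log2 changes are given with limma's moderated standard error (SE). Where a probe was not well above background on any array in the dimmer role, the fold is a bound. It is the mean of the brighter role over the mean of the higher of the probe's own signal and the lowest signal well above background on each array, after loess and Aquantile normalization.

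These choices, the gene lists, most of the alternatives and the rule for named genes were made before the data were examined. They included that a rat whose arrays, oriented by the labels, correlate below -0.3 over the tested probes has no settled direction and leaves the fit. The arrays of rat 15 correlated at -0.42, so the fit rests on rats 8 and 17 (n = 2 rats, 4 arrays). Fits with rat 15 are given as alternatives. The extraction session coincides with the rat in this fit, so session and rat cannot be told apart there. The values of rat 8 are those of the first session and the values of rat 17 those of the second. A session term was fitted only over all 6 arrays.

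Probes were named through the reference table of genes, by RefSeq accession for 8064 probes, by gene identifier for 8666, by symbol for 1392 and by synonym for 421. That makes 18543 named probes. The other 22469 kept the name in the array design, which can be old. No coordinates are given. The text names, 1 probe per gene, the 12 highest and the 12 lowest changes past the threshold with both fitted rats in the direction. It also names the 2 members of each list with the largest change past the threshold, or those with the smallest p if none passed, and a fixed set of genes of flow response, smooth muscle and remodelling. The rule was written for 3 rats and was applied to 2. Of the fixed set, Edn1, Acta2, Mki67, Tnc and Pdgfb had no tested probe under these symbols. 1 gene list and 1 gene that the rule names are not reported here. Genes outside the rule serve as examples within a list and were chosen after their values were seen.

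The 27 gene lists stand for cell types that a dissected artery can hold and for pathways of vessel remodelling. Each was tested with camera, with a preset correlation between genes of 0.01 and the tested probe of highest mean intensity standing for a gene. The p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With 2 rats, both rest for each gene on the difference between the rats. They have little power, and a missing call there decides nothing. A list of cytosolic ribosomal proteins was added after seeing the data. Probes are not independent replicates, so correlations across probes have no p.

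The procedure was tested on simulated data with 20515 probes and 2 rats, in which 200 probes were changed. It called 92.5% of the 67 probes changed 2-fold, 100% of the 67 changed 4-fold and 100% of the 66 changed 8-fold. Of its 219 calls, 24 were false, a larger share than the threshold allows. It called the shifted gene list and 0 of 20 unshifted lists. The simulated probes were independent and had no brightness trend, and the shifted list held only raised probes. The list result therefore does not measure false calls among correlated genes.

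The alternatives set in advance were no background correction, the software's processed signals, median centring, scaling between arrays, the authors' value table, no filter and a stricter filter on dim probes, outlier spots kept, array-level fits with the rat as a random block with and without a dye term, other treatments of rat 15, replicates left out, other moderation, other thresholds and other set tests. Others were chosen after seeing the data: rat 15 as labelled or with its first array turned, its second array joined to 1 of the other rats, each of the 4 arrays left out, a filter over those 4 arrays, dye and session terms with rat 15's first array turned, and ratios centred on the running median of the 101 tested probes nearest in brightness.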

Results

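RNA of shunt collateral arteries and RNA of control arteries from the same animal were hybridised together on each array, with 2 arrays for each of rats 8, 15 and 17. The stated purpose was to find genes that answer to the shear stress of flowing blood. On rat 8's arrays, 39.4% and 56.0% of probes were well above background in the shunt channel and 18.7% and 16.6% in the control channel. On rat 17's arrays the shares were 77.4% and 54.9% for shunt and 75.1% and 35.5% for control. On rat 15's arrays, read by the labels, they were 6.90% and 42.0% for shunt and 47.0% and 19.3% for control. The number of arrays limits the precision.

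In rats 8 and 17, 17 of 27 skeletal muscle markers, 8 of 38 extracellular matrix genes and 6 of 22 macrophage markers were higher in shunt collaterals than in control arteries past the threshold. Other transcripts were lower, and no gene list was called with an estimated correlation between genes, a test with little power at 2 rats. Acta1, the actin of skeletal muscle, rose by 2.95 on the log2 scale (SE 0.37, n = 2 rats, 7.74-fold, limma adjusted p = 0.00448). Sparc, a matrix protein of tissue remodelling, rose by 1.68 (SE 0.14, 3.20-fold, adjusted p = 0.000656), and Lyz2, the lysozyme of macrophages, rose by 1.26 (SE 0.19, 2.39-fold, adjusted p = 0.00969). Gsn, which encodes the actin-severing protein gelsolin, fell by 4.26 (SE 0.13, 19.2-fold, adjusted p = 7.53e-06). Gsn had no value on rat 17's second array, so the value of rat 17 is that of its first array alone. Cst3, which encodes the protease inhibitor cystatin C, fell by 2.44 (SE 0.14, 5.42-fold, adjusted p = 0.000133).

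Of 20515 probes tested, 757 passed the threshold, 535 higher and 222 lower in shunt collaterals. They carried 275 gene names among the higher and 107 among the lower. At least a 2-fold change was seen for 259 of the higher and 109 of the lower probes. All 4 arrays had the same direction for 707 of the 757, where measured. The control artery was not well above background on any of the 4 arrays for 10 of the higher probes, and the shunt collateral for 1 of the lower. The share of higher calls, 70.7%, moved with the scaling: the counts of higher and lower probes were 196 and 0 with median centring, 219 and 13 with the authors' value table and 848 and 200 with the software's processed signals. They were 429 and 454 with ratios centred by brightness, a setting chosen after seeing the data. The median of all tested log2 ratios was 0.025 with loess, 0.15 with median centring, 0.14 with the authors' value table and 0.10 with the processed signals.

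Rat 8 and rat 17 correlated across tested probes at Pearson's r = 0.55 and a Spearman correlation of 0.30. Between the arrays of 1 rat, r was 0.49 in rat 8, 0.33 in rat 17 and -0.42 in rat 15. Over the probes bright in both channels on all 6 arrays, r was 0.84, 0.51 and -0.75. Rat 15 therefore had no settled direction and stayed outside the fit. Apart from its first array, arrays of different rats with shunt labelled in the same dye correlated at 0.67, 0.55, 0.31 and 0.24. Arrays of different rats with shunt in different dyes correlated at 0.43, 0.29, 0.23 and 0.075. Dye effects may therefore enter the ratios of single arrays. The reported fit has no dye term, but it averages arrays with exchanged dyes within rats 8 and 17. An additive dye effect therefore cancels for probes with a value on both arrays of a rat. It does not cancel where an array has no value, such as for Gsn (rat 17's second array), Rplp1l2 (rat 8's first) and Myl1, Sod3, Cox8a, Ifi27 and Gja5 (rat 17's first). Of the called probes, 665 of 752 had the fitted direction on rat 15's second array and 23 of 756 on its first, read by the labels. Of the probes not called, 12949 of 19671 and 7590 of 19743 did. With rat 15 as labelled 0 probes passed in limma (959 with an unadjusted p under 0.05), and with its first array turned 27 did, 13 higher and 14 lower, both fits chosen after seeing the data. No probe passed when outlier spots were kept (2284 with an unadjusted p under 0.05) or without rat 17's second array (1505). The counts of higher and lower were 210 and 40 without rat 8's first array, 134 and 98 without its second, and 771 and 618 without rat 17's first.

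**Figure D1:**
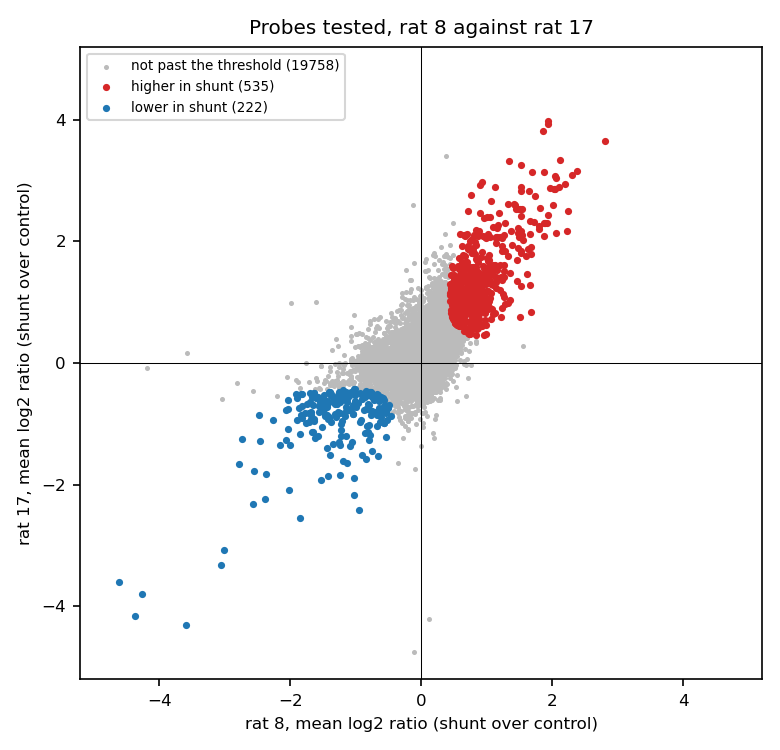
Mean log2 ratio of shunt over control in rat 17 (vertical axis) against rat 8 (horizontal axis) for the 20515 tested probes, 1 of which lies outside the axes. Red points are the 535 probes higher and blue points the 222 lower in shunt collaterals, and grey points did not pass the threshold.

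The highest changes among named genes were led by Rab15, a small GTPase, at 3.22 (SE 0.19, 9.34-fold, adjusted p = 0.000168), although its other probe was at 0.043. Contractile genes of striated muscle made up most of the other places. Myh6 (2.55) and Myh7 (2.09) encode myosin heavy chains of the heart and slow muscle, Myh1 (2.03) a myosin heavy chain of fast muscle and Myl1 (2.24) a light chain. Tnnc2 (2.20) and Tnnc1 (2.17) encode the calcium-binding troponins of fast and slow muscle. Msl3l2 (2.44), Gdnf (2.43), which encodes a neurotrophic factor, Clic1 (2.03) and Tuba4a (2.02) completed the 12. The SE of these changes was between 0.13 and 0.37 and their adjusted p was at most 0.00448. The other probe of Gdnf was at -0.047 and that of Clic1 at 0.49, and Msl3l2 was at -1.59 on rat 15's second array.

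**Figure D2:**
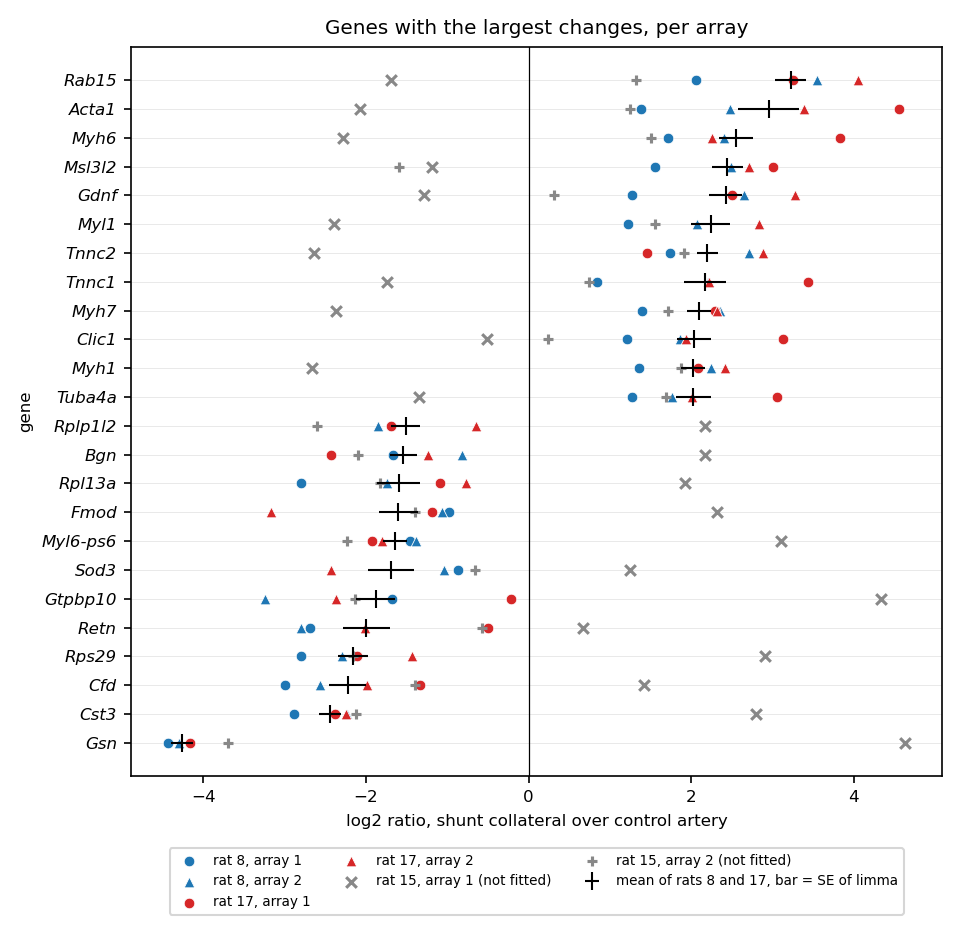
Log2 ratio of shunt over control (horizontal axis) per array for the 12 highest and 12 lowest named genes (vertical axis), with the mean of rats 8 and 17 and the SE of limma in black. Blue and red symbols are the arrays of rats 8 and 17, and grey crosses are the arrays of rat 15, whose first array lies opposite to the fitted mean for every gene shown. With median centring Bgn, Rpl13a, Rps29, Rplp1l2 and Myl6-ps6 lay above 0.

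Skeletal muscle markers formed the list with the largest shift. Of 27 measured members 17 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.98 and a camera adjusted p of 2.01e-22. The list had adjusted p = 0.765 with an estimated correlation. Beside the genes above, Mybpc1 (1.96) and Ampd1 (1.76) rose, which encode a myosin-binding protein and a muscle enzyme of AMP metabolism, with their other probes at 0.24 and -0.014. The bright members Tnni2 (0.10), Actn3 (-0.036) and Eno3 (0.061) did not pass with loess, and were at 0.99, 0.83 and 0.46 with ratios centred by brightness. The median was 0.66 in rat 8, 1.15 in rat 17, -1.28 on rat 15's first array as labelled and 0.72 on its second. With the preset correlation the list kept its camera call in each alternative tested except with rat 15's second array turned (adjusted p = 0.186) and with rat 15's first array alone (0.562), which bring rat 15 in with the first array's labelled sign.

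Other genes of the actin cytoskeleton and of muscle were measured apart from these markers. Fhl1, an adaptor abundant in muscle, rose by 1.38 (SE 0.28, adjusted p = 0.0326) and Actn1, an actin crosslinker, by 0.86 (SE 0.13, adjusted p = 0.00957). The other probes of Fhl1 were at 0.54 and 0.44 and that of Actn1 at 0.14. Abra, which encodes an actin-binding protein of striated and smooth muscle, was at 1.40 (SE 0.34, adjusted p = 0.0685) and did not pass. Its values were 0.48 in rat 8 and 2.31 in rat 17. Ccn2 rose by 0.82 and Actb by 0.80 (other probe 1.07).

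Genes of oxidative phosphorylation were at a median of 0.40, with 0.16 in rat 8, 0.56 in rat 17, and -0.35 and 0.20 on rat 15's arrays as labelled. The skeletal muscle medians, 0.66, 1.15, -1.28 and 0.72, stood in the same order, as did the hypoxia medians of 0.061, 0.16, -0.053 and 0.099. Lists without a call also stood in this order, such as endothelial markers (-0.033, 0.13, -0.081 and 0.0080) and immediate early genes (-0.024, 0.17, -0.096 and 0.024). The order is therefore not particular to muscle genes. Of 41 oxidative phosphorylation genes measured, 3 rose and 2 fell (23 and 3 adjusted over the list alone), and camera gave an adjusted p of 4.40e-05. The list had adjusted p = 0.894 with an estimated correlation, and its camera call ended over probes bright on all arrays (adjusted p = 0.806) and with ratios centred by brightness (0.0974). Cox4i1 rose by 0.86 (other probe 0.15) and Cox8a fell by 1.21, both subunits of cytochrome c oxidase. Of 19 hypoxia-responsive genes 2 rose and 0 fell, also adjusted over the list alone, with a median of 0.12 and a camera adjusted p of 0.0215 (adjusted p = 0.894 with an estimated correlation). The hypoxia call ended without rat 8's second array (adjusted p = 0.0652), without rat 17's first (0.117), with the rat as a random block (0.0751), with ratios centred by brightness (0.170) and in several fits with rat 15. The higher genes were the glycolytic genes Aldoa (1.34) and Ldha (0.77), and Vegfa was at 0.12. Among 20 genes of the unfolded protein and heat shock response 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 4.40e-05 (adjusted p = 0.765 with an estimated correlation). Cryab (1.18) and Hspb1 (1.03, other probe 0.17), small heat shock proteins abundant in muscle, led them, followed by the chaperones Pdia6 (1.01) and Hspa5 (0.68).

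Some extracellular matrix genes rose. Of 38 measured, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 0.000197. The list had adjusted p = 0.765 with an estimated correlation, and a median of 0.018 on rat 15's second array. Sparc rose by 1.68, Fn1, which encodes fibronectin, by 1.47 (SE 0.25, adjusted p = 0.0138), Col4a1 by 1.40 (other probe 0.64) and Col3a1 by 1.13, whereas Col14a1 fell by 0.66. Bgn, the proteoglycan biglycan, fell by 1.54 (SE 0.16, adjusted p = 0.00213), but was at 1.02 with median centring and at 0.085 with the authors' value table. Col1a1 was at 0.24 on its brightest probe and 1.17 on the other, which passed (adjusted p = 0.00256). The second probe of Sparc was at 0.37 and that of Fn1 at 1.06, and without rat 17's first array Fn1 was at 0.91. Among 20 matrix proteases and inhibitors 1 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.090 and a camera adjusted p of 0.858. Timp1, a metalloproteinase inhibitor, rose by 1.22 (SE 0.15, adjusted p = 0.00367), Timp2 fell by 1.28 (SE 0.13, adjusted p = 0.00167, 0.70 with median centring), and Mmp2 was at 0.087 (other probe 0.35).

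Among smooth muscle genes the synthetic and contractile lists differed in their calls, and the difference between them was not tested. Of 13 synthetic genes 4 rose and 0 fell, also adjusted over the list alone, with a median of 0.13 and a camera adjusted p of 0.00759 (adjusted p = 0.765 with an estimated correlation). Vim, the filament protein vimentin, rose by 1.57 (SE 0.16, adjusted p = 0.00184) and Spp1, osteopontin, by 1.00 (SE 0.13, adjusted p = 0.00462). On rat 15's second array Vim was at 0.016 and Spp1 at 0.14. Without rat 8's second array the synthetic list's adjusted p was 0.0731, and without rat 17's second array 0.232. Of 20 contractile genes 2 rose and 1 fell (3 and 2 adjusted over the list alone), with a camera adjusted p of 0.858, a median of 0.069 and a camera direction that was downward. With median centring its median was 0.52 and camera's direction upward (adjusted p = 0.0221). Des, the muscle filament protein desmin, rose by 1.05 (SE 0.20, adjusted p = 0.0233) beside the skeletal muscle markers, and Csrp1 fell by 1.10 (SE 0.18, adjusted p = 0.0117, 0.28 with median centring). Myh11, the smooth muscle myosin heavy chain, was at 0.23 (other probe 0.37). The list of genes of cell division had 2 of 20 higher and 0 lower, also adjusted over the list alone, with a median of 0.12 and a camera adjusted p of 0.0481 (adjusted p = 0.894 with an estimated correlation). Cdk1, the mitotic kinase, rose by 0.72 with its other probe at 0.038, Cdkn3 was at least 1.51-fold higher (adjusted p = 0.0357, control not well above background), and Ccnd1 was at 0.21 (other probe -0.043). The cell division list lost its camera call without any 1 of the 4 arrays, with adjusted p between 0.0580 and 0.155.

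Some macrophage markers and antigen presentation genes were higher in shunt collaterals. Of 22 monocyte and macrophage markers 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.27 and a camera adjusted p of 4.40e-05 (adjusted p = 0.765 with an estimated correlation). On rat 15's second array the list's median was 0.065. Lyz2 rose by 1.26 and C1qa, a complement component made by macrophages, by 1.00 (SE 0.13, adjusted p = 0.00466, second probe 0.95), Laptm5 by 0.75 and Tyrobp by 0.70 (other probe -0.21). Cd68 was at 0.69 (SE 0.16, adjusted p = 0.0547) and did not pass, with 1.73 and 0.20 on rat 17's arrays. Of 8 class II genes 3 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.63 and a camera adjusted p of 4.40e-05 (adjusted p = 0.765 with an estimated correlation). Cd74, the class II invariant chain, rose by 1.28 (SE 0.20, adjusted p = 0.00983) and RT1-Da by 0.94 (SE 0.13, adjusted p = 0.00583). On rat 15's second array the class II median was -0.018, with Cd74 at -0.085 and RT1-Da at 0.11. Without rat 17's first array the changes of Cd74 and RT1-Da were 0.78 and 0.58. No member passed, also adjusted over the list alone, among 11 lymphocyte markers (median 0.086, camera adjusted p = 0.738), 5 mast cell markers (0.075, 0.893), 10 neutrophil and erythroid markers (-0.013, 0.738) or 21 chemokines, cytokines and adhesion molecules (0.047, 0.858). Cd3d was at 0.39, Lck at 0.21, Tpsb2 at 0.25, Kit at -0.39, Mpo at -0.23, Slc4a1 at -0.16, Cxcl12 at -0.58 (other probe 0.075), Ccl2 at 0.082, Icam1 at 0.10, Vcam1 at -0.011 and Cd44 at 0.17. The arrays of rat 17 had opposite signs for Cxcl12, at 0.63 and -1.35. Il1b did not pass, with a 95% interval from -0.030 to 0.56 on the log2 scale before adjustment. As the control was not well above background, its estimate is a bound of at least 1.05-fold. This bound leaves out the interval, so no rise is shown. In the interferon response list 1 of 13 rose and 0 fell, also adjusted over the list alone (median 0.083, camera adjusted p = 0.711), which was Ifi27 at 0.79.

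Endothelial genes and genes known to respond to flow moved both ways. Of 16 endothelial markers 1 rose and 1 fell, also adjusted over the list alone (median 0.087, camera adjusted p = 0.893). Cldn5, a tight junction protein, rose by 1.20 (SE 0.18, adjusted p = 0.00884), and Vwf, von Willebrand factor, fell by 0.85 (SE 0.16, adjusted p = 0.0265). The arrays of rat 17 had opposite signs for Vwf, which was at -0.50 without the second. Of 18 flow-responsive genes 1 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.040, camera adjusted p = 0.858). Gja5, the arterial gap junction protein connexin 40, rose by 1.28 (SE 0.15, adjusted p = 0.0035), and Thbd, thrombomodulin, fell by 0.68 (SE 0.14, adjusted p = 0.0317). Gja5 had no value on rat 17's first array. On rat 15's second array Gja5 was at 0.087 and Cldn5 at 0.00086, and Thbd (0.14) and Vwf (0.59) were opposite to the fitted direction. Klf2 (0.036), Klf4 (-0.097) and Nos3 (0.15), which are known to rise with laminar shear in endothelium, did not pass. They were dim, with mean log2 intensities of 6.43, 6.96 and 6.59. Of the 17774 tested probes below 7, 62 were called higher and 47 lower. A missing call at this brightness does not show that a gene was unchanged. The calcium channel gene Trpv4 was at 0.42 (SE 0.17, adjusted p = 0.316), with a 95% interval from 0.034 to 0.81 before adjustment. Its arrays were at -0.097 and 0.29 in rat 8 and at -0.074 and 1.57 in rat 17. Of 15 ion channel, connexin and calcium handling genes 1 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.738), Gja5 and the calcium release channel Itpr1, which fell by 0.67 with its other probe at 0.024. Itpr1 was at -0.27 without rat 17's second array. Of 11 nitric oxide genes 0 rose and 1 fell, also adjusted over the list alone (median 0.065, camera adjusted p = 0.858 with a downward direction). Ddah2 fell by 0.74, and was at 0.15 with median centring and at -0.31 without rat 17's second array.

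The lists of growth factors, immediate early genes, cholesterol synthesis and nerve markers had 0 or 1 member past the threshold. None of 30 growth factors and receptors passed, also adjusted over the list alone (median 0.042, camera adjusted p = 0.858), with Pdgfa at 0.34, Kdr at -0.44, Fgf2 at -0.079 and Fgfr1 at -0.0059. Among 20 immediate early genes 1 rose and 0 fell, also adjusted over the list alone (median 0.084, camera adjusted p = 0.711). This was Cebpd at 0.79, whereas Fos was at 0.20 and Egr1 at 0.048. Fos, Fgf2 and Fgfr1 were dim, with mean log2 intensities of 6.49, 6.11 and 6.41, so their missing calls decide little. None of 10 cholesterol synthesis genes passed, also adjusted over the list alone (median -0.017, camera adjusted p = 0.858), with Idi1 at 0.27 and Msmo1 at 0.26. None of 14 nerve and Schwann cell markers passed, also adjusted over the list alone (median 0.060, camera adjusted p = 0.893 with a downward direction), with Prph at -0.49 and Gfap at -0.26.

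Genes of fat and connective tissue made up part of the lowest changes. Of 15 adipocyte markers 0 rose and 3 fell, also adjusted over the list alone, with a median of -0.057, a camera adjusted p of 0.0109 and adjusted p = 0.765 with an estimated correlation. The call ended with scaling between arrays (adjusted p = 0.0519), with no filter (median -0.028) and in most fits with rat 15, such as with its second array alone (0.0966). Cfd, which encodes the adipocyte protease adipsin, fell by 2.22 (SE 0.23, adjusted p = 0.00192), Retn, which encodes resistin, by 1.99 (SE 0.29, adjusted p = 0.00722) and Adipoq, adiponectin, by 0.86. Fabp4 was at -0.073 and Lpl at -0.028, and with median centring the list median was 0.035. Of 15 fibroblast and adventitia markers 0 rose and 3 fell, also adjusted over the list alone, with a camera adjusted p of 0.0996. The median of 0.031 was opposite in sign to the mean of -0.38 and to camera's direction. Its lower members were Gsn, Fmod, the collagen-binding fibromodulin, which fell by 1.60 (SE 0.24, adjusted p = 0.00798), and Col14a1. The other genes among the 12 lowest were Rps29 (-2.16), Gtpbp10 (-1.88), Sod3 (-1.69), the extracellular superoxide dismutase, Myl6-ps6 (-1.64), Rpl13a (-1.60) and Rplp1l2 (-1.51). Rps29, Rpl13a, Rplp1l2 and Myl6-ps6 lay between 0.24 and 0.66 with median centring, and the other probes of Rps29 were at -0.40 and -0.27. The second probe of Cst3 fell by 2.06.

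**Figure D3:**
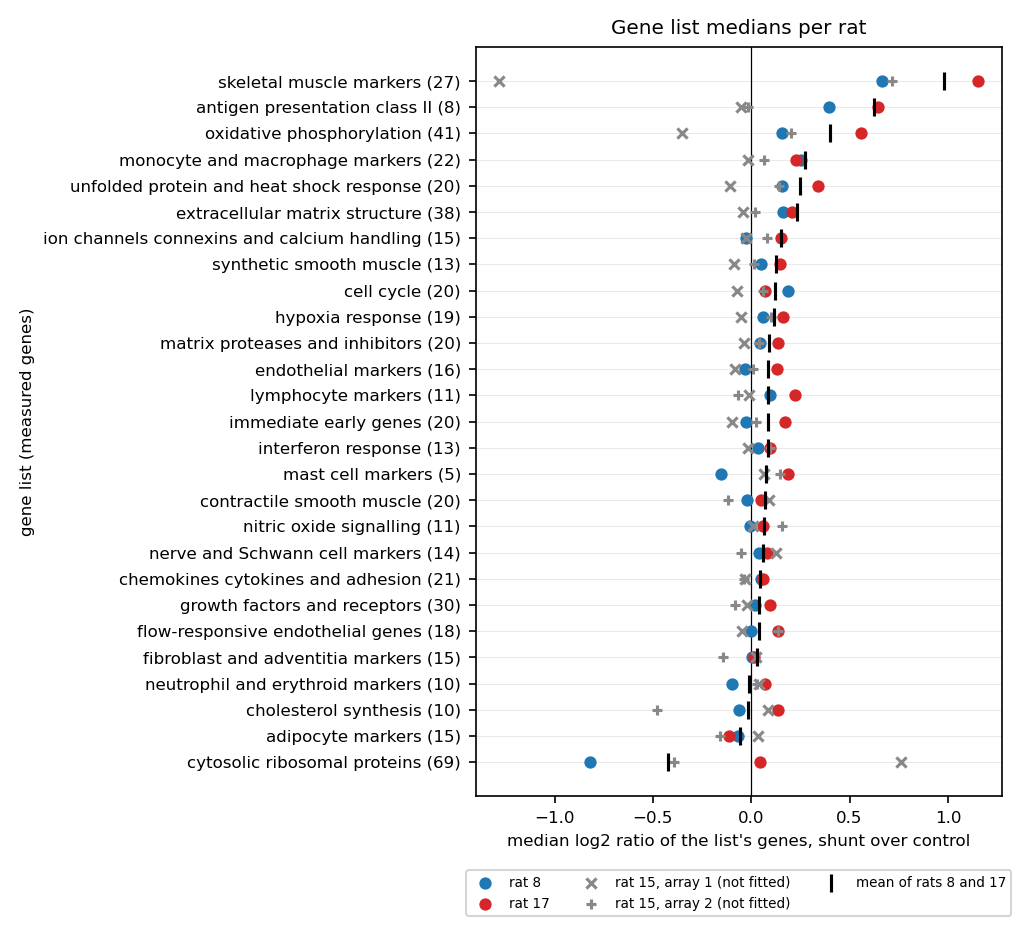
Median log2 ratio of shunt over control (horizontal axis) of the gene lists (vertical axis, measured genes in parentheses) in rats 8 and 17, their mean, and the 2 arrays of rat 15 as labelled. The skeletal muscle median is 0.66 in rat 8 and 1.15 in rat 17, and the added ribosomal protein list, at -0.42, lies at 1.31 with median centring.

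Camera with the preset correlation called 11 of the 27 lists. None was called with an estimated correlation or with fry, whose smallest adjusted p was 0.178 for a shift one way and 0.121 for change in either direction. With 2 rats these tests had little power, so the missing calls decide nothing for or against a list.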

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

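All tests in this part were chosen after the results were seen. Each value below lay apart from the other arrays by more than Dixon's 95% critical value. Of 122 values examined 26 did. Of these, 13 lie on rat 15's first array, which the labels put in the same dye orientation as its second. A chance rate of about 1 in 20 does not apply to these counts, since the values are not independent. The 12 genes flagged on that array were also named for changes past the threshold in the fitted rats. That array ran opposite to the mean of the fitted rats, so the choice of genes favours values apart on it. On rat 15's first array Tnnc2 was at -2.64, Myh7 at -2.37, Myh1 at -2.66 and Actn1 at -1.17 as labelled. The other arrays had 0.33 or more. In the other direction Gsn was at 4.63, Myl6-ps6 at 3.10, Rps29 at 2.91, Cst3 at 2.79, Bgn at 2.17, Timp2 at 1.99, Csrp1 at 1.59 and Cox8a at 1.44, where the other arrays had -0.48 or less. The skeletal muscle list's median was -1.28 there, against 0.51 to 1.40 on the other 5 arrays.

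The opposition of rat 15's arrays held across the transcripts that changed in the other rats. The correlation of the arrays over probes bright in both channels was -0.754, which a dye effect alone does not give between arrays of the same labelled orientation. As labelled, the second array correlated at 0.388 with the mean of rats 8 and 17, which argues against a wrong label there. The first array correlated at -0.685 with that mean, so a candidate explanation is that its dyes, or its shunt and control samples, are exchanged in the labels. A true difference of rat 15 is not tested apart from this, but the arrays hold the same extracts, and its direction stays unsettled.

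Rat 17's first array was the brightest of the 6. Its median signal was 294.5 in Cy3 and 354.4 in Cy5, against at most 94.7 and 67.4 on the others. Its median background was 58 in Cy3 and 72 in Cy5, and 5.97% of its spots were marked as outliers, against at most 1.80% elsewhere. On it Cd68 was at 1.73 against at most 0.47 on the other arrays, and Kit at -1.18 against at least -0.35. The median of the matrix protease list was 0.53, that of the immediate early genes 0.325 and that of the hypoxia list 0.40. On rat 17's second array Trpv4 was at 1.57, against at most 0.29 on the others. On rat 8's first array Mpo was at -1.07 against at least -0.075 elsewhere, and the neutrophil and erythroid list's median was at -0.12.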

How the results depend on the processing

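The fits with rat 15 as labelled or with its first array turned, with its second array joined to 1 other rat, with single arrays left out, with a filter over the 4 fitted arrays, with ratios centred by brightness, and the dye and session terms with the first array turned were chosen after seeing the data; the others were planned. Values are counts of probes past the threshold (535 higher and 222 lower as reported) and list medians in log2; the cause of a change was not tested unless named. The calls rest on 2 rats: 0 probes passed in limma with outlier spots kept (2284 with an unadjusted p under 0.05, smallest adjusted p 0.0568), with rat 15 as labelled (959), with its second array turned (126), with its first array alone (140), with its second array joined to rat 17 only (907), with a dye term over all 6 arrays as labelled (1043) and without rat 17's second array (1505). Of the 757 called probes, the direction held for 656 with median centring, for 710 with the authors' value table, for 753 with ratios centred by brightness and for all of them with outlier spots kept or rat 15 as labelled. The prior degrees of freedom of limma were 7.49 in the reported fit, 3.70 with outlier spots kept and 3.84 with no filter. With the rat as a random block, the routine returned no correlation within rats for a dye term on the 4 arrays of rats 8 and 17, so this fit was run over all 6 arrays, and no fit of a dye term without that block was run. A session term could not be fitted on the 4 arrays because session and rat coincide. Dim signal limits the ratios: of 41012 probes, 1753 were well above background in both channels on all 6 arrays. Leaving out rat 15 (replicate 2) is the fit as reported, and leaving out rat 8 or rat 17 (replicates 1 and 3) leaves 1 rat and values with no test. Each array holds the shunt and control RNA of the same rat, so the fit as reported is already paired within rats, and no unpaired fit was run.

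Without background correction 294 probes were higher and 95 lower. With the processed signals 848 were higher, and the fibroblast list (0.22) passed downward. With median centring 196 were higher and 0 lower, the contractile smooth muscle list turned upward (0.52) and the cell cycle list (0.29) lost its call. The ribosomal list was then at 1.31, Ddah2 at 0.15, Csrp1 at 0.28, Timp2 at 0.70, Rplp1l2 at 0.24, Bgn at 1.02, Rpl13a at 0.66, Myl6-ps6 at 0.39 and Rps29 at 0.26, all opposite to their reported direction. With scaling between arrays 128 were lower, and the adipocyte list (-0.046) lost its call. With the authors' value table, 219 were higher and 13 lower, the correlation of rats 8 and 17 was 0.311, the ribosomal list was at 0.44 and Bgn at 0.085. Median centring differs from loess by construction in how it treats bright probes. With no filter 63 were higher and 25 lower, and the cell cycle (0.037) and adipocyte (-0.028) lists lost their calls, over 40974 probes. With the stricter filter 1752 probes were tested, 129 were higher and 144 lower, and the correlation of rats was 0.803. Over these fewer genes 2 lists were called, fibroblast markers passed downward (-0.66), and synthetic smooth muscle (0.13), extracellular matrix (0.24), oxidative phosphorylation (0.051) and unfolded protein (0.37) lists lost their calls. With outlier spots kept the counts were 0 and 0 and the ribosomal list was at 0.0014.

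With arrays as units and the rat as a random block 93 were lower, and the synthetic smooth muscle (0.044) and hypoxia (0.11) lists lost their calls. With a dye term over the 6 arrays as labelled the counts were 0 and 0, and the same 2 lists were at 0.025 and 0.068. With the dye term and rat 15's first array turned 62 were higher, 32 lower and 7 lists called. The session term with that array turned gave 992 higher, 573 lower and 7 lists. In both of these fits synthetic smooth muscle (-0.0039), cell cycle (0.11), adipocyte (-0.097) and hypoxia (0.093) lists lost their calls. With ratios centred by brightness 454 were lower, and the cell cycle (0.078), hypoxia (0.058) and oxidative phosphorylation (0.081) lists lost their calls. With the filter over the 4 arrays the cell cycle list was at 0.060, and with the mean of all probes of a gene at 0.085, past the threshold in neither. At an adjusted p under 0.1, 350 were lower, and with at least a 2-fold change 259 were higher and 109 lower.

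With rat 15's second array turned the counts were 0 and 0 and 5 lists were called. The lists that lost their calls were skeletal muscle (0.33), cell cycle (0.086), adipocyte (0.0029), hypoxia (0.080), oxidative phosphorylation (0.14) and unfolded protein (0.10). With its first array alone the counts were 0 and 0, 4 lists were called, Gtpbp10 turned to 0.19 and the ribosomal list to 0.022. Skeletal muscle (0.26), synthetic smooth muscle (0.24), cell cycle (0.092), hypoxia (0.064), oxidative phosphorylation (0.12) and unfolded protein (0.095) lists lost their calls. With its second array alone 4 were higher and 9 lower, and synthetic smooth muscle (0.017), cell cycle (0.086) and adipocyte (-0.12) lists lost their calls. With rat 15 as labelled the counts were 0 and 0, 7 lists were called, and synthetic smooth muscle (0.095), cell cycle (0.086), adipocyte (-0.083) and hypoxia (0.10) lists lost their calls. With its first array turned 13 were higher and 14 lower, and synthetic smooth muscle (0.082), cell cycle (0.087) and adipocyte (-0.097) lists lost their calls. With its second array and rat 8 only, 11 were higher and 57 lower and 4 lists were called. Synthetic smooth muscle (0.066), cell cycle (0.14), extracellular matrix (0.12), adipocyte (-0.16), class II (0.20), hypoxia (0.067) and oxidative phosphorylation (0.18) lists lost their calls. With its second array and rat 17 only the counts were 0 and 0, synthetic smooth muscle (0.019), cell cycle (0.067) and extracellular matrix (0.14) lists lost their calls, fibroblast markers (-0.094) passed downward and Vwf was at 0.016.

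With an estimated correlation and with fry 0 lists were called. The medians do not change in these tests: synthetic smooth muscle 0.13, cell cycle 0.12, extracellular matrix 0.23, macrophage 0.27, skeletal muscle 0.98, adipocyte -0.057, class II 0.63, hypoxia 0.12, oxidative phosphorylation 0.40 and unfolded protein 0.25. Over the replicates and single arrays left out, the count higher ranged from 0 to 771, the count lower from 0 to 618 and the correlation of rats from 0.338 to 0.644. The list medians ranged from 0.033 to 0.23 for synthetic smooth muscle, 0.068 to 0.19 for cell cycle, -0.0096 to 0.031 for fibroblast, 0.049 to 0.26 for hypoxia, 0.20 to 0.30 for macrophage, 0.059 to 0.22 for lymphocyte, 0.049 to 0.13 for chemokine, 0.0057 to 0.097 for growth factor, -0.11 to -0.015 for adipocyte and -0.064 to 0.13 for cholesterol lists. They ranged from -0.033 to 0.13 for endothelial, -0.031 to 0.13 for contractile smooth muscle, 0.10 to 0.28 for extracellular matrix, -0.0081 to 0.081 for nitric oxide, -0.027 to 0.15 for ion channel, 0.40 to 0.67 for class II, -0.020 to 0.094 for interferon and -0.82 to 0.043 for ribosomal protein lists. Without rat 8's second array the synthetic smooth muscle (0.033), cell cycle (0.11) and hypoxia (0.14) lists lost their calls, and fibroblast markers (0.026) passed downward. The cell cycle list also lost its call without any 1 of the other arrays (0.11 to 0.19), the hypoxia list without rat 17's first (0.049) and the synthetic smooth muscle list without its second (0.062). The medians also ranged from 0.16 to 0.56 for oxidative phosphorylation, 0.66 to 1.15 for skeletal muscle, 0.16 to 0.41 for unfolded protein, -0.15 to 0.19 for mast cell, -0.030 to 0.24 for matrix protease, -0.096 to 0.071 for neutrophil and erythroid, -0.027 to 0.17 for immediate early, -0.021 to 0.13 for flow-responsive and -0.0074 to 0.13 for nerve lists. Moderation with an intensity trend and robust settings gave 481 higher and 326 lower, both within 1.5 times the reported counts. Only 428 of the 757 reported calls were among them. No list lost or gained a call with this moderation or without background correction. Of the 87 named genes, 73 kept their direction and side of the threshold without background correction, 75 with the processed signals, 51 with median centring, 57 with the value table, 83 with ratios centred by brightness and 32 with outlier spots kept. The 8 reversed with median centring, Bgn with the value table, Gtpbp10 and Vwf are the reversals among them in the alternatives run.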

Other observations

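The weighing tests, the ribosomal protein list and the comparisons by brightness in this part were chosen after the results were seen. Genes for proteins of the cytosolic ribosome leaned low in shunt collaterals with loess, among the fitted rats in rat 8 only. Of 69 measured 3 rose and 21 fell (11 and 32 adjusted over the list alone), with a median of -0.42 and a camera adjusted p of 8.71e-10 (adjusted p = 0.890 with an estimated correlation). The median was -0.82 in rat 8 and 0.043 in rat 17. Rpl37 fell by 1.42, Rpl35 by 1.40 and Rps27 by 1.37, whereas Rps4x rose by 1.19, Rpl4 by 0.90 and Rpl15 by 0.89. With median centring the list's median was 1.31, with the value table of the authors 0.44 and with the processed signals -0.14, so its direction depends on the scaling.

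Bright probes leaned low after loess in general, and probes of middle brightness leaned high. The median log2 ratio was 0.37 for the 474 tested probes with a mean log2 intensity of 8 to 9, -0.14 for the 192 from 9 to 10, -0.71 for the 92 from 10 to 11 and -1.01 for the 62 above 11. With median centring the medians of these bins were 1.46, 1.43, 1.27 and 1.47. For the 1921 probes from 7 to 8 the loess median was 0.25. Of the higher calls 284 lay from 7 to 8 and 134 from 8 to 9, against 64 and 18 lower calls. Against random lists matched on brightness, the loess medians of the called synthetic smooth muscle, hypoxia and adipocyte lists lay at percentiles 73.3, 89 and 6.28. The other called lists lay at 99.17 or higher. With median centring the synthetic smooth muscle, hypoxia and adipocyte lists lay at 99.05, 95.22 and 0.85. The oxidative phosphorylation list was then at 86.66 and the other called lists at 97.18 or higher. Which called lists stand apart from their brightness therefore depends in part on the scaling. Across the ribosomal genes brightness and the log2 ratio correlated at -0.845 (genes are not independent). Among 10000 random lists matched on brightness the ribosomal median lay at percentile 0.15 with loess and 34.0 with median centring. It lay at 0.56 with the processed signals, 0.11 without background correction and 9.42 with the value table. The matched lists had a median of -0.087 with loess, and with ratios centred by brightness the ribosomal median was -0.12 (camera adjusted p = 0.0179). A brightness trend left by the normalization is a candidate explanation of part of the shift, and the rest stays open. Dye bias alone does not give it, since the list median was -0.61 on arrays with shunt in Cy5 and -0.337 on those with shunt in Cy3. No biological explanation was tested.

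The skeletal muscle markers are the pattern a reader would most want to follow up, since muscle surrounds these arteries, none of its 33 genes stands in another list used here, and 12 of its 27 measured genes were well above background in the control arteries on all 4 arrays. Over the 9 members bright on all arrays the median was 0.477, with a camera adjusted p of 0.0328. With an estimated correlation it was 0.758, a test with little power at 2 rats. With loess Tnni2, Actn3, Eno3 and Pvalb were near 0. They were at 0.99, 0.83, 0.46 and -0.33 with ratios centred by brightness and at 2.46, 2.25, 1.00 and 0.95 with median centring. Their values depend on the scaling and do not decide how far a dim control channel contributes, which stays open. The list median was 0.736 on arrays with shunt in Cy5 and 1.21 on those with shunt in Cy3, which argues against dye bias as the only source. Muscle tissue carried along in the shunt samples, with Acta1, Ckm and Mb among its most abundant transcripts (2.95, 0.79 and 1.08), may account for the shift. It cannot be told apart from a change in the vessel wall here: the 8 brightest members had a median of 0.635 with loess, with some of them near 0, and 2.36 with median centring.

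Turning the signs of the fitted rats, with the arrays of a rat together, gives 2 patterns, so no share under 0.5 is possible. The labelled pattern called 757 probes and the other called 0, so the number of patterns with as many calls was 1.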
